A study of Homo sapiens with 6 samples.

How the data were processed

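RNA was measured by poly-A-selected sequencing in 6 libraries from THP-1 cells, a human monocytic leukaemia line. The series' design text says that the cells were differentiated into macrophages and that pyroptosis, a lytic inflammatory cell death, was induced with lipopolysaccharide (LPS) and ATP. Per the labels, 3 libraries came from cells also given ruxolitinib, a JAK1 and JAK2 kinase inhibitor, and 3 from cells without it, called control here. The treatment field spells the drug differently from the series title, and the sample titles carry its abbreviation. Drug dose, exposure times and the differentiating agent are not given in the sources used here. Untreated cells without LPS and ATP were not analysed here, so both groups are stimulated and no baseline stands beside them.

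The authors deposited whole-number read counts per gene in 1 table of 61517 genes, and every row names a gene. Per the submitters' processing notes, the genome build was hg38. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, a gene and an overlapping antisense gene cannot be separated. Genes with near-identical copies, among them the metallothioneins, the HLA genes and the IFITM genes, carry the same caution. Total counts per library were 17757595, 24533979 and 22780991 in control replicates 1 to 3 and 19253534, 19041988 and 18796476 in ruxolitinib replicates 1 to 3. A count of 0 in a library allows a level of up to 0.122 to 0.169 CPM, taking 3 counts as the upper limit, and such limits cover counting error only. Gene coordinates came from GENCODE 29 on GRCh38, in which 58340 of the gene identifiers were found.

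Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, robust). Scaling used TMM factors, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14051 genes. P-values were adjusted over these genes by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values of genes come from this test unless another is named. Standard errors (SE) of log2 fold changes were derived from the coefficient and its F statistic. Levels are CPM over TMM-scaled totals, as mean ± SD over 3 libraries per group. Positive log2 fold changes mean higher with ruxolitinib. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

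A set of 28 gene lists was fixed before the data were examined. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. Each was tested again with an estimated correlation, and with fry, which asks whether the members of a list move on balance in one direction. With an estimated correlation, camera also takes its degrees of freedom from the residuals, which are few with 6 libraries. A call lost there can reflect this as well as correlation between members. RIGI was found in the table under its older symbol DDX58. Named genes followed a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and groups that do not overlap. It adds up to 4 members per list with the smallest adjusted p and a fixed group of inflammasome, cytokine and JAK-STAT genes. Some genes that met this rule are not reported here. MEFV, CARD16, CXCL8, CXCL9, IDO1, STAT4, CSF1R and CD14 were added after their values were seen.

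The labels give each library a batch number, 1 to 3, shared by a control and a ruxolitinib library, and the numbers pair the libraries on that ground. In the data, the deviations of same-numbered libraries from their group means had correlations over genes of -0.02, -0.19 and -0.10, so the pairing rests on the label alone. The fit without the batch as a block was fixed as the main one, and the blocked fit was an alternative. Other alternatives were median-ratio factors, upper-quartile scaling, library totals alone, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, counts thinned to the smallest total, removal of the 10 most abundant genes, and leaving out each library and each batch pair. Removal of mitochondrial genes was added after seeing the data.

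The procedure was tested on simulated counts with 200 changed genes. With trended dispersions over 13821 genes, it recovered 36.7% of genes changed 1.25-fold, 59.6% at 1.5-fold, 79.2% at 2-fold and 100% at 4-fold, and 4.70% of its calls were unchanged genes. With gene-wise dispersions over 13800 genes the shares were 26.5%, 53.1%, 63.3% and 98.0%, and 15.4% of calls were unchanged genes. A list of 30 members shifted 1.25-fold was called under both, and 0 of 20 unshifted lists. The simulated genes were drawn independently, so this does not show how often lists with correlated members are called wrongly. The simulation also changed far fewer genes than the 4175 called in the data. The adjusted threshold depends on that share, so the simulated shares may not carry over. Chi-square values per degree of freedom between libraries of a group ran from 3.20 to 19.5, so no library repeated another within sampling noise.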

Results

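The libraries held 17757595 to 24533979 counts, with 23153 ± 1466 genes detected in control and 21306 ± 157 with ruxolitinib (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Correlations of log2 CPM over genes were 0.988 to 0.991 within a group and 0.972 to 0.976 between groups, and the first principal component, with 57.3% of the variance, separated control from ruxolitinib. The 10 most abundant genes took 15.5% ± 0.471 of the counts in control and 17.4% ± 0.351 with ruxolitinib (exact two-sided permutation p = 0.1). The comparison asked how ruxolitinib changed the transcripts of THP-1 macrophages stimulated with LPS and ATP.

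Of the 28 gene lists, type I interferon-stimulated genes had the largest median fall with ruxolitinib. IFI44L, an interferon-induced gene, fell from 161 ± 6.60 to 0.515 ± 0.0278 CPM, a log2 fold change of -8.27 ± 0.09 (SE, n = 3 per group, adjusted p = 8.4e-14). IFIT1, which binds viral RNA, fell from 298 ± 10.5 to 2.30 ± 0.652 CPM (log2 fold change -7.01 ± 0.11). In all, 4175 of 14051 genes (29.7%) passed the threshold, 1908 higher and 2267 lower. A log2 fold change of at least 1 in size was found for 571 of them, 154 higher and 417 lower, and of those at 3 or beyond 57 were lower and 0 higher. The median size of change among the genes past the threshold was 0.41. The groups did not overlap for 44.2% of genes, against 10% by chance. Without both libraries of batch 1, 1983 genes passed, 840 higher and 1143 lower.

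**Figure D1:**
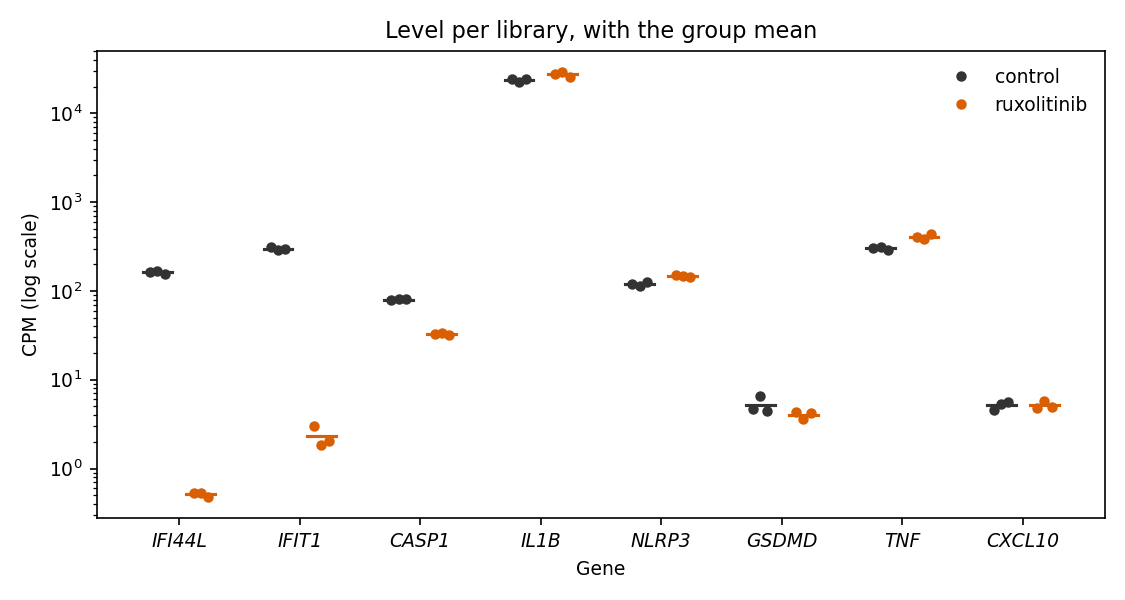
Level of 8 genes in each library, in CPM on a log axis, with control in black and ruxolitinib in orange; each point is a library and each bar the mean of 3. IFI44L, IFIT1 and CASP1 lay lower in every ruxolitinib library, and CXCL10 lay at 5.15 and 5.19 CPM on average.

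All 43 tested members of the type I interferon-stimulated list fell, with a median log2 fold change of -3.58 (camera adjusted p = 2.4e-47), and adjusted over the list alone the count was also 43. The adjusted p = 0.016 with an estimated correlation, and 0.0939 with the batch as a block as well. Among genes past the threshold with a mean of at least 1 CPM and groups that do not overlap, the 10 largest falls were IFI44L, IFIT1, OAS1, IFIT5, OAS2, GBP5, IFIT3, EPSTI1, USP18 and PARP9. OAS1 and OAS2, which make the activator of RNase L, lie on chromosome 12 at 112906777 to 112933222 and 112978395 to 113011723, and fell by 5.80 ± 0.10 and 5.63 ± 0.08 on the log2 scale. IFIT1 (chromosome 10, 89392546 to 89406486), IFIT3 (89327894 to 89340971) and IFIT5 (89414586 to 89421001) are neighbours, and the last 2 had log2 fold changes of -5.52 ± 0.07 and -5.77 ± 0.10. IFI44L lies on chromosome 1 at 78619922 to 78646145. USP18, which dampens interferon receptor signalling, fell from 41.8 ± 1.68 to 1.03 ± 0.509 CPM. OAS3 fell from 732 ± 7.68 to 31.9 ± 1.93 CPM and IFI44 from 258 ± 8.99 to 7.31 ± 0.683 CPM.

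Of 29 tested interferon gamma target genes, 21 fell, 6 rose and 2 did not pass (median -0.90, camera adjusted p = 3.1e-06), with the same counts adjusted over the list alone. The adjusted p = 0.0495 with an estimated correlation, and 0.167 with the batch as a block as well. GBP5, a guanylate-binding protein, fell by 5.61 ± 0.18 on the log2 scale, GBP1 by 3.18 ± 0.10, the aminopeptidase gene LAP3 by 2.01 ± 0.06 and APOL6 by 1.71 ± 0.07. The members that rose included CXCL9, a chemokine near the detection limit (0.274 ± 0.170 to 1.28 ± 0.375 CPM, log2 fold change 2.26 ± 0.47), and the tryptophan-degrading enzyme gene IDO1 (1.13 ± 0.06). The chemokine gene CXCL10 was at 5.15 ± 0.573 CPM in control and 5.19 ± 0.482 CPM with ruxolitinib (log2 fold change 0.00 ± 0.14, adjusted p = 0.988). The interferon genes IFNB1 and IFNG were too low to test: IFNB1 had 5 counts in the 3 control libraries and 3 with ruxolitinib, and IFNG had 0 and 1. Counts of other interferon genes are not reported here.

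Among 27 JAK-STAT pathway components, 11 fell, 2 rose and 14 did not pass (camera adjusted p = 0.028), or 13 lower and 4 higher adjusted over the list alone, and 8 lower and 1 higher with the batch as a block. The adjusted p = 0.259 with an estimated correlation, 0.054 with the batch as a block, 0.0801 without control replicate 3, and 0.0535 and 0.0798 without both libraries of batch 1 or 3. STAT2 fell by 1.14 ± 0.08 on the log2 scale, CSF2RB, the shared receptor chain for GM-CSF, IL-3 and IL-5, by 1.68 ± 0.11, and the interleukin-6 receptor gene IL6R by 0.63 ± 0.04, while STAT4 rose by 0.75 ± 0.07. The drug's targets moved little. JAK2 had a log2 fold change of -0.28 ± 0.07 (adjusted p = 0.0125, but 0.0845 without control replicate 1, 0.0742 without ruxolitinib replicate 1, and 0.246 and 0.0539 without both libraries of batch 1 or 3). JAK1 had -0.16 ± 0.05 (adjusted p = 0.0258, but 0.103 with the block, 0.0636 with median-ratio and 0.0697 with upper-quartile scaling, 0.0908 by DESeq2, 0.114 and 0.172 without control replicates 1 and 3, 0.126 and 0.0839 without ruxolitinib replicates 1 and 3, and 0.263 and 0.220 without both libraries of batch 1 or 3), and STAT3 -0.10 ± 0.05 (adjusted p = 0.156, but 0.0469 with library totals alone and 0.0496 without both libraries of batch 2). Of 16 JAK-STAT feedback genes and STAT3 or STAT5 targets, 7 fell, 2 rose and 7 did not pass (camera adjusted p = 0.244), or 7 lower and 3 higher adjusted over the list alone, and 6 lower and 1 higher with the block. By fry that list was lower (adjusted p = 0.0466). CISH, a STAT5-induced signalling inhibitor, fell from 2.94 ± 0.339 to 0.107 ± 0.107 CPM, IL1RN, the interleukin-1 receptor antagonist, from 1806 ± 29.3 to 956 ± 112 CPM, and the transcriptional repressor gene BCL6 from 315 ± 26.5 to 185 ± 13.9 CPM. SOCS3, a feedback inhibitor, fell by 0.66 ± 0.11 on the log2 scale. SOCS1 was too low to test, with 24 counts in control and 23 with ruxolitinib.

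Members of the pyroptosis and inflammasome machinery moved in both directions. Of 30 tested, 12 fell, 5 rose and 13 did not pass, and the list as a whole did not pass (median -0.16, camera adjusted p = 0.0925), although it did without ruxolitinib replicate 2 (adjusted p = 0.0449), without both libraries of batch 2 (0.0335) and by fry (0.00265). The camera adjusted p was 0.708 with an estimated correlation. Adjusted over the list alone, 13 fell and 7 rose, and with the batch as a block 10 fell and 2 rose. CASP1, the protease that cleaves pro-interleukin-1 beta and gasdermin D (chromosome 11, 105025443 to 105035250), fell from 79.9 ± 0.454 to 32.7 ± 1.02 CPM (log2 fold change -1.29 ± 0.05, adjusted p = 3.7e-09). AIM2, a cytosolic DNA sensor, fell from 5.81 ± 0.923 to 0.265 ± 0.137 CPM (-4.43 ± 0.29), the Toll-like receptor adaptor gene MYD88 from 86.5 ± 2.99 to 37.8 ± 1.59 CPM (-1.19 ± 0.06), and TXNIP from 474 ± 12.4 to 273 ± 10.9 CPM (-0.80 ± 0.05). The pyrin gene MEFV fell by 0.89 ± 0.16 on the log2 scale, CARD16 by 0.46 ± 0.09, and PYCARD, the adaptor ASC (chromosome 16, 31201485 to 31203450), by 0.44 ± 0.11. The PYCARD call was lost by DESeq2 (adjusted p = 0.0712) and without both libraries of batch 1 (0.0836) or batch 3 (0.0524).

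NLRP3, the inflammasome sensor (chromosome 1, 247416156 to 247449108), rose from 121 ± 6.50 to 147 ± 3.56 CPM (log2 fold change 0.29 ± 0.05, adjusted p = 0.00123, but 0.0641 without both libraries of batch 1). NINJ1, which mediates plasma membrane rupture, rose by 0.45 ± 0.06 on the log2 scale. IL1B (chromosome 2, 112829751 to 112836903) was among the most abundant transcripts, at 23600 ± 960 CPM in control and 27433 ± 1720 CPM with ruxolitinib (log2 fold change 0.22 ± 0.06, adjusted p = 0.0119). That call was lost with the block (adjusted p = 0.0924), without ruxolitinib replicate 1 (0.0605) and without both libraries of batch 1 (0.173). IL18 was low, at 2.37 ± 0.370 and 3.57 ± 0.528 CPM (0.60 ± 0.19, adjusted p = 0.0354). Its call was lost with the block (0.0927), by DESeq2 (0.137) and without control replicate 2 (0.104), control replicate 3 (0.0631), ruxolitinib replicate 1 (0.0647), ruxolitinib replicate 2 (0.137) or both libraries of batch 1 (0.0942), 2 (0.248) or 3 (0.0834). GSDMD, the pore-forming executioner (chromosome 8, 143553207 to 143563062), had 5.25 ± 1.18 and 4.05 ± 0.353 CPM (-0.38 ± 0.18, adjusted p = 0.128). The related GSDME had -0.19 ± 0.07 (adjusted p = 0.0469, but 0.125 with the block, 0.259 by DESeq2, 0.0542 by limma-voom, 0.0741 with median-ratio and 0.0991 with upper-quartile scaling, 0.110 with no filter on low counts, 0.0604 without mitochondrial genes, between 0.0655 and 0.211 when any single library was left out, and 0.370 and 0.112 without both libraries of batch 1 or 3). CASP4, a sensor of cytosolic LPS, had 0.05 ± 0.05 (adjusted p = 0.463) and the ATP-gated channel gene P2RX7 0.46 ± 0.27 (adjusted p = 0.227).

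**Figure D2:**
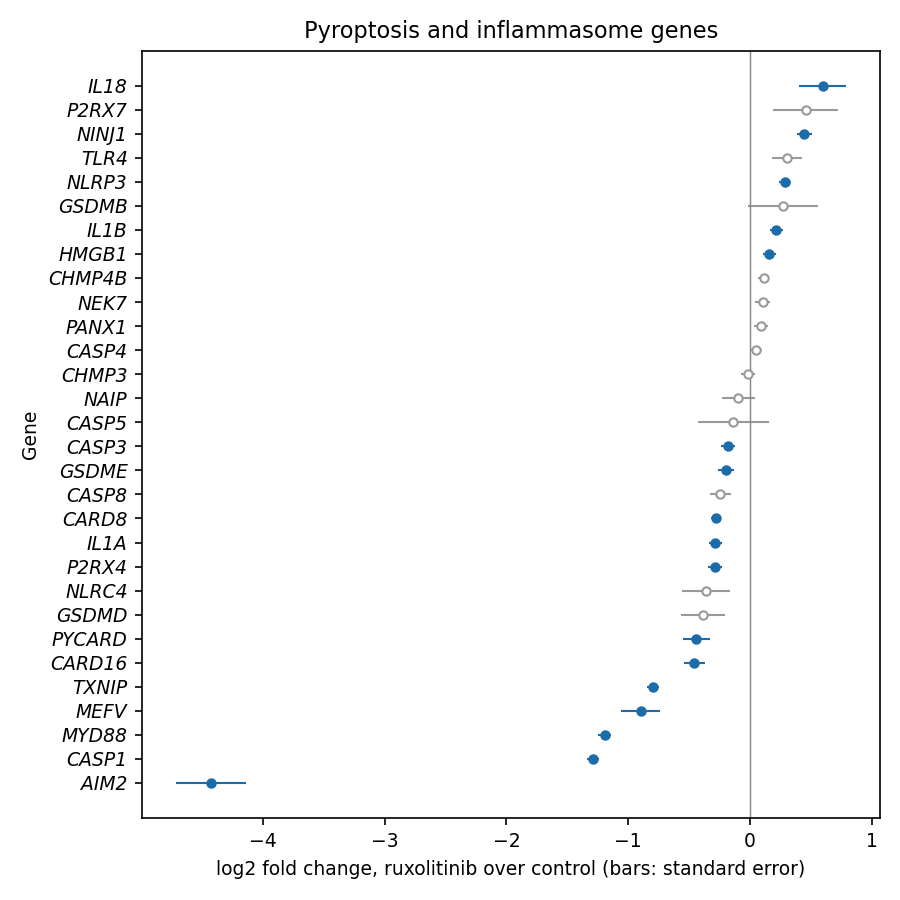
Log2 fold change, ruxolitinib over control, of the 30 tested pyroptosis and inflammasome genes, with bars for the standard error. Filled points mark adjusted p under 0.05, of which 12 lay below 0 and 5 above.

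NF-kB-driven cytokine and feedback genes were more often higher than lower. Of 38 tested, 19 rose, 9 fell and 10 did not pass (median 0.24, camera adjusted p = 0.00327), and adjusted over the list alone 21 rose and 9 fell. The adjusted p = 0.12 with an estimated correlation. IL23A, a subunit of interleukin-23, rose from 501 ± 13.5 to 1475 ± 52.7 CPM (log2 fold change 1.56 ± 0.05), the chemokine gene CCL20 by 0.94 ± 0.05 on the log2 scale, and BIRC3, an inhibitor of apoptosis, by 0.89 ± 0.06. TNF (chromosome 6, 31575567 to 31578336) rose from 301 ± 9.47 to 407 ± 25.8 CPM (0.43 ± 0.05, adjusted p = 6.7e-05), and CXCL8, the most abundant transcript, rose by 0.49 ± 0.07. CCL2, a monocyte chemoattractant, fell from 68.1 ± 2.18 to 5.59 ± 0.589 CPM (-3.61 ± 0.08), and IL6 (chromosome 7, 22725884 to 22732002) by 0.60 ± 0.07 (adjusted p = 3.2e-05).

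Genes of MHC class I antigen presentation and macrophage markers were lower as lists, and MHC class II genes did not pass as a list by camera. Of 19 tested genes of MHC class I and antigen processing, 16 fell and 3 did not pass (median -0.52, camera adjusted p = 6.7e-08), or 17 lower and 1 higher adjusted over the list alone. They included the peptide transporter genes TAP1 (log2 fold change -0.87 ± 0.05) and TAP2 (-0.69 ± 0.05), the immunoproteasome subunit gene PSMB8 (-0.60 ± 0.05) and the chaperone gene CALR (-0.52 ± 0.04). Of 30 macrophage and monocyte markers, 21 fell, 3 rose and 6 did not pass (median -0.62, camera adjusted p = 5.8e-07), or 23 lower and 3 higher adjusted over the list alone. The lectin gene SIGLEC1 fell by 4.29 ± 0.16 on the log2 scale, the lysosomal genes CTSL, CD68 and CTSB by 1.11 ± 0.04, 1.10 ± 0.04 and 0.64 ± 0.04, the M-CSF receptor gene CSF1R by 1.15 ± 0.09 and the LPS co-receptor gene CD14 by 0.78 ± 0.05. Among the 3 that rose was APOE, from 1.41 ± 0.398 to 3.36 ± 0.260 CPM (log2 fold change 1.24 ± 0.23). Both lists had adjusted p = 0.0256 with an estimated correlation, and 0.167 with the batch as a block as well. Of 20 IL-4 and STAT6 alternative activation genes, only 7 were high enough to test. With ruxolitinib, CCL17 had 2 counts and CISH, which is also in the JAK-STAT feedback list, had 6. All 7 fell, also adjusted over the list alone (camera adjusted p = 8.7e-06), among them the decoy receptor gene IL1R2 (-1.01 ± 0.05) and the transglutaminase gene TGM2 (-0.97 ± 0.09). The adjusted p = 0.12 with an estimated correlation. Of 12 MHC class II genes, 5 fell, 1 rose and 6 did not pass (camera adjusted p = 0.236), the same adjusted over the list alone, but the list was lower by fry (adjusted p = 0.00468). The invariant chain gene CD74 fell by 0.60 ± 0.08 and the co-stimulatory gene CD86 rose by 0.53 ± 0.08.

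**Figure D3:**
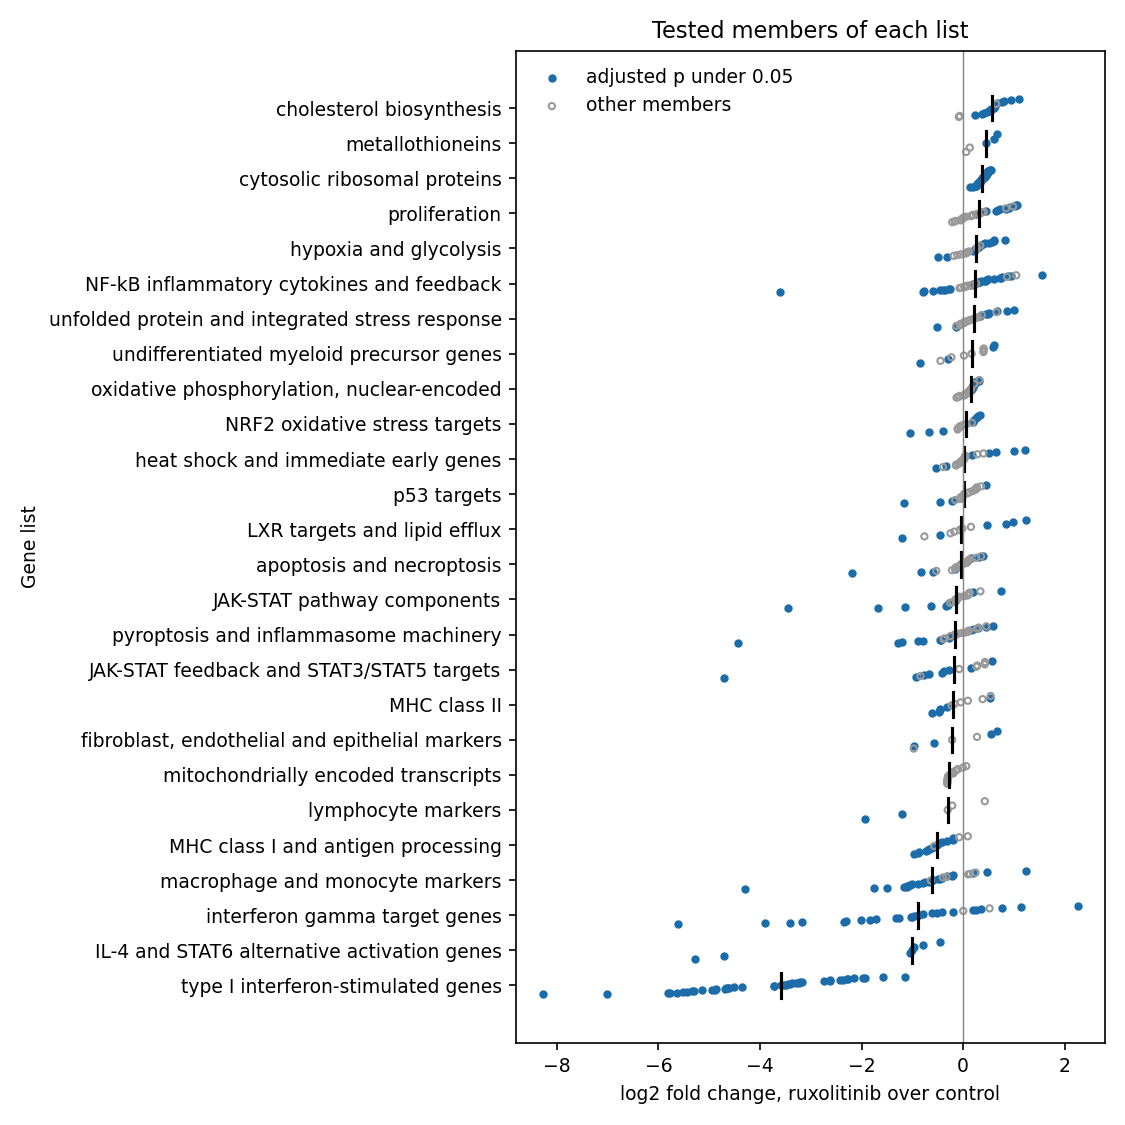
Log2 fold change, ruxolitinib over control, of the tested members of each list with at least 5 of them. Filled points mark adjusted p under 0.05, open points the other members and black bars the median, which ran from -3.58 for type I interferon-stimulated genes to 0.58 for cholesterol biosynthesis.

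Cholesterol biosynthesis genes rose together. Of 20 tested, 17 rose and 3 did not pass (median 0.58, camera adjusted p = 5.1e-10), or 18 higher adjusted over the list alone, and the adjusted p = 0.0256 with an estimated correlation and 0.167 with the batch as a block as well. HMGCS1 rose from 150 ± 7.90 to 321 ± 21.7 CPM (log2 fold change 1.09 ± 0.06), MSMO1 by 0.95 ± 0.05 and FDFT1 by 0.77 ± 0.05. Of 12 LXR targets and lipid efflux genes, 4 rose, 2 fell and 6 did not pass (camera adjusted p = 0.923), or 4 higher and 5 lower adjusted over the list alone. The desaturase gene SCD rose by 0.85 ± 0.05 and the cholesterol exporter gene ABCA1 fell by 0.45 ± 0.05. Of 25 hypoxia and glycolysis genes, 14 rose, 2 fell and 9 did not pass (camera adjusted p = 5.9e-05), or 15 higher and 2 lower adjusted over the list alone. The adjusted p = 0.0791 with an estimated correlation. ENO1, a glycolytic enzyme gene, rose by 0.61 ± 0.05 and ALDOC by 0.82 ± 0.07.

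Of 30 proliferation genes, 12 rose and 18 did not pass (median 0.31, camera adjusted p = 5.8e-05), the same adjusted over the list alone, and the adjusted p = 0.044 with an estimated correlation and 0.174 with the batch as a block as well. The topoisomerase gene TOP2A rose from 5.49 ± 0.659 to 10.4 ± 0.979 CPM and the thymidylate synthase gene TYMS from 2.73 ± 0.295 to 5.59 ± 0.537 CPM. Of 11 undifferentiated myeloid precursor genes, 2 rose, 2 fell and 7 did not pass (camera adjusted p = 0.607), the same adjusted over the list alone. The homeobox genes HOXA9 and HOXA10 rose by 0.59 ± 0.07 and 0.61 ± 0.13 (HOXA10 adjusted p = 0.0942 without both libraries of batch 1), and with the block 2 were higher and 0 lower. Of 25 apoptosis and necroptosis genes, 4 fell, 3 rose and 18 did not pass (camera adjusted p = 0.607), or 5 lower and 3 higher adjusted over the list alone. By fry that list was lower (adjusted p = 2.1e-04). The death ligand gene TNFSF10 fell by 2.19 ± 0.09 and MLKL, the executioner of necroptosis, by 0.83 ± 0.10. Of 19 p53 targets, 3 fell, 1 rose and 15 did not pass (camera adjusted p = 0.607), the same adjusted over the list alone.

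Of 25 genes of the unfolded protein and integrated stress response, 8 rose, 2 fell and 15 did not pass (camera adjusted p = 0.00144), the same adjusted over the list alone, and 7 rose and 1 fell with the block. The adjusted p = 0.0719 with an estimated correlation. The chaperone genes DNAJB9 and HSPA5 rose by 1.01 ± 0.05 and 0.50 ± 0.04, and the transcription factor gene XBP1 by 0.66 ± 0.04. Of 5 metallothionein genes, 3 rose and 2 did not pass (camera adjusted p = 0.0128), the same adjusted over the list alone. The adjusted p = 0.12 with an estimated correlation, 0.0542 without control replicate 2 and 0.124 without both libraries of batch 2. Of 17 NRF2 oxidative stress targets, 7 rose, 3 fell and 7 did not pass (camera adjusted p = 0.607), the same adjusted over the list alone, and the haem oxygenase gene HMOX1 fell by 0.67 ± 0.04. Of 23 heat shock and immediate early genes, 5 rose, 2 fell and 16 did not pass (camera adjusted p = 0.36), the same adjusted over the list alone, and 4 rose and 1 fell with the block. By fry that list was higher (adjusted p = 0.0466). The nuclear receptor gene NR4A2 rose by 1.01 ± 0.08.

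All 41 tested cytosolic ribosomal protein genes rose, also adjusted over the list alone, by a median of 0.37 (camera adjusted p = 2.1e-17), among them RPLP0 from 466 ± 13.8 to 669 ± 27.3 CPM. The adjusted p = 0.267 with an estimated correlation, which was 0.769 in this list. Of 32 nuclear-encoded oxidative phosphorylation genes, 15 rose and 17 did not pass (camera adjusted p = 3.1e-04), or 18 higher and 1 lower adjusted over the list alone, and 5 rose with the block. The adjusted p = 0.374 with an estimated correlation. None of the 13 mitochondrially encoded transcripts passed, 0 also adjusted over the list alone (camera adjusted p = 0.304, and 0.00361 without ruxolitinib replicate 3 and 0.00439 without both libraries of batch 3). Mitochondrial transcripts took 5.90%, 5.56% and 5.27% of counts in control and 4.94%, 3.75% and 6.42% with ruxolitinib (exact two-sided permutation p = 0.6, smallest possible 0.1).

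Few markers of other cell types were high enough to test. Of 5 tested lymphocyte markers, 2 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0342). The adjusted p = 0.246 with an estimated correlation, 0.0542 with the block, 0.477 with no filter on low counts, 0.121 without ruxolitinib replicate 1, and 0.147 and 0.0624 without both libraries of batch 1 or 2. The interleukin-7 receptor gene IL7R fell from 73.5 ± 4.50 to 32.0 ± 0.605 CPM and NKG7 from 5.68 ± 0.661 to 1.49 ± 0.393 CPM. Of 7 fibroblast, endothelial and epithelial markers, 2 rose, 2 fell and 3 did not pass (camera adjusted p = 0.796), or 2 higher and 3 lower adjusted over the list alone, and 1 rose with the block. By fry that list was lower (adjusted p = 0.0462). PECAM1, also made by monocytes, fell by 0.57 ± 0.05 on the log2 scale. The platelet chemokine gene PPBP, the 1 tested erythroid and megakaryocyte marker, fell from 21.1 ± 0.838 to 6.29 ± 0.382 CPM. Of 4 neutrophil and mast cell markers, 1 fell, also adjusted over the list alone, and 3 did not pass (camera adjusted p = 0.627). It was S100A12 (adjusted p = 0.0372, and 0.0506 with the block, 0.157 by DESeq2, 0.0731 with counts thinned to the smallest total, 0.115 without control replicate 1, 0.0545 without control replicate 2, 0.0879 without ruxolitinib replicate 1, 0.121 without ruxolitinib replicate 3, and 0.199 and 0.113 without both libraries of batch 1 or 3).

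Under the same limits on level and overlap, the 10 largest rises were smaller than the 10 largest falls. EMP2, a membrane protein gene (chromosome 16, 10528422 to 10580698), rose from 3.34 ± 0.582 to 12.8 ± 1.29 CPM (log2 fold change 1.94 ± 0.15, adjusted p = 1.4e-06). G0S2, an inhibitor of triglyceride lipase (chromosome 1, 209675420 to 209676388), rose from 12.1 ± 0.977 to 46.1 ± 2.96 CPM (1.93 ± 0.08). P2RY10, C3orf80, TCIM, NPTX2, PPFIA2 and the unnamed gene ENSG00000237927 had log2 fold changes of 1.68 to 2.23. ZACN (1.74 ± 0.39, adjusted p = 0.0872 with the block) and ENSG00000228144 (2.25 ± 0.64) completed the 10. Both calls were lost under several settings. For ZACN the adjusted p was 0.0921 without control replicate 3, 0.0712 without ruxolitinib replicate 1, 0.0571 without ruxolitinib replicate 3, 0.0751 and 0.159 without both libraries of batch 1 or 3 and 0.0565 with no filter on low counts. For ENSG00000228144 it was 0.0513 and 0.0692 without control replicates 2 and 3 and 0.0688 and 0.0892 without ruxolitinib replicates 1 and 2, 0.101 without both libraries of batch 3 and 0.0757 by limma-voom.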

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

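Removing the mitochondrial genes was an alternative chosen after seeing the data; the others were fixed before. Of 132 named genes with a test, 126 passed the threshold. Of these, 106 passed with the same sign under each of the 20 other settings that gave them an adjusted p. While past the threshold, 0 named genes changed sign. In 19 cases, counted over named genes and list tests together, a value past no threshold changed sign. All 43 type I interferon-stimulated genes stayed lower under every setting.

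With the batch as a replicate block, 2915 genes passed (1288 higher, 1627 lower), 2905 of them also without it. Pyroptosis members higher then numbered 2. The block ended no camera call of a list other than JAK-STAT components and lymphocyte markers. DESeq2 called 3100 genes, 3010 of them shared, and limma-voom 4173, of which 4097 were shared. Scalings gave 4120 (median-ratio), 4275 (upper-quartile) and 4199 (library totals) genes, with 48.4%, 54.2% and 37.6% of them higher against 45.7%. No filter gave 4459, the CPM filter 4148, thinning 4074, removal of the 10 most abundant genes 4170 and of mitochondrial genes 4149.

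Leaving out a library or a batch pair gave 1983 to 5034 genes, 840 to 2553 higher and 1143 to 2481 lower. The lowest values, 1983, 840 and 1143, came without both libraries of replicate 1, and the highest, 5034, without both of replicate 2, which leaves as many libraries. Pyroptosis members higher ranged from 1 to 7 (1 without both libraries of replicate 1, and 3 without those of replicate 2 or of replicate 3) and members lower from 7 to 12 (7 without both libraries of replicate 1). The pyroptosis camera adjusted p ranged from 0.0335 to 0.433, with 0.0449 without ruxolitinib replicate 2 and 0.0335 without both libraries of replicate 2; fry, which asks another question, gave 0.00265. The cause was not tested. The NF-kB list had adjusted p = 0.12 with an estimated correlation, against 0.00229 to 0.0137 with libraries left out. With an estimated correlation, the calls of the type I interferon, interferon gamma, MHC class I, macrophage, proliferation and cholesterol lists held, and those of the other lists past the threshold were lost. Correlation alone does not explain the losses, as that form of the test has few degrees of freedom. The unfolded protein and metallothionein lists lost their calls with estimated correlations of -0.00955 and -0.0368, below the preset 0.01. With the block and an estimated correlation together no list passed by camera, the lowest adjusted p being 0.0939, and the block leaves fewer degrees of freedom still. The JAK-STAT feedback, MHC class II, apoptosis, heat shock and fibroblast lists did not pass by camera but passed by fry. At this depth the smallest simulated changes were recovered for 36.7% of genes with trended and 26.5% with gene-wise dispersions, so small differences can go unseen. The simulation changed 200 genes, far fewer than the 4175 called in the data, so these shares may not hold for this comparison.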

Other observations

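The gene families and genes in this and the next paragraph were chosen after their values were seen, as were all tests here except the splits of the libraries and the correction for gene length and GC content. Cathepsin genes, which encode lysosomal proteases, were lower with ruxolitinib: 8 of 11 tested fell and 3 did not pass (median log2 fold change -0.45, camera adjusted p = 1.1e-04, and adjusted p = 0.078 with an estimated correlation). CTSH fell from 551 to 302 CPM and CTSZ from 742 to 446 CPM. Of 7 leukocyte immunoglobulin-like receptor genes, 6 fell and 1 did not pass (median -1.06, camera adjusted p = 3.4e-04, and adjusted p = 0.124 with an estimated correlation). Of 13 PARP genes, 6 fell (camera adjusted p = 3.4e-04, and adjusted p = 0.078 with an estimated correlation), and of 37 tripartite motif genes 12 fell and 2 rose (camera adjusted p = 0.00504, and adjusted p = 0.0841 with an estimated correlation). PARP9, PARP12, PARP14 and TRIM22 are also in the type I interferon-stimulated list, and CTSB, CTSD and CTSL are among the macrophage markers. The families therefore partly repeat those lists. These families kept the sign of their median under the 3 other scalings.

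Chemokines split by gene. Of 12 CC chemokine genes, 6 fell and 5 rose (camera adjusted p = 0.539), and of 11 CXC chemokine genes 4 fell and 3 rose (camera adjusted p = 0.842). CCL1 fell from 90.1 ± 3.23 to 17.8 ± 0.647 CPM and CXCL16 from 41.0 to 25.9 CPM. The DNA sensor gene IFI16 fell from 275 ± 13.8 to 18.2 ± 1.74 CPM, and TNFSF13B, the B-cell survival factor BAFF, from 37.8 ± 1.18 to 5.39 ± 1.12 CPM. The alarmin genes IL33 and TSLP rose from 6.62 ± 0.0803 to 19.2 ± 1.61 CPM and from 1.60 ± 0.367 to 4.69 ± 0.535 CPM. TNFRSF10D, a decoy receptor for the product of TNFSF10, rose from 42.5 ± 0.167 to 129 ± 0.963 CPM. Of 13 EIF3 translation initiation subunits, 8 rose (camera adjusted p = 0.00103, and adjusted p = 0.166 with an estimated correlation), and all 3 tested PDE4 phosphodiesterase genes rose (camera adjusted p = 0.00504, and adjusted p = 0.0841 with an estimated correlation).

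The 41 ribosomal protein genes rose together. Removing the trend of fold change on GC content and exonic length left their median at 0.38, and 41 of 41 stayed above 0. Gene length and GC content are thus argued against as the whole cause. The lowest median under the 3 other scalings and the removal of the most abundant or the mitochondrial genes was 0.34. Scalings shift all genes nearly alike, and the median of all tested genes stayed between -0.048 and 0.023 under these 3. That comparison therefore shows only that the choice among them matters little. The group difference of the mean level of the ribosomal protein genes was 2.67 times the larger range within a group. That range comes from 3 libraries per group that may not be separate cultures, so a difference between cultures was not excluded. Reads shared with ribosomal protein pseudogenes were not tested and stay open, beside a candidate explanation in which the drug itself raises these transcripts. The camera call was lost with an estimated correlation (adjusted p = 0.267).

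IL7R, NKG7, TRGC1 and TRGC2 are associated with lymphocytes and were lower with ruxolitinib; TRGC1 had 101 counts in control and 3 with ruxolitinib, and TRGC2 125 and 8. T cells in the control cultures are argued against as the source of the TRGC1 and TRGC2 counts: CD3D, CD3E and CD3G, of the T-cell receptor complex, had 0 counts in control, which allows at most 3, or 1.33% of those 226 counts. TRBC1 and TRBC2 also had 0 in control. Other genes of the complex did have counts, TRAC 393 in control and 289 with ruxolitinib and CD247 59 and 49, or 6.04 and 5.06 CPM for TRAC and 0.907 and 0.858 CPM for CD247; where these come from was not tested. A candidate explanation is lower output of STAT5 targets within the THP-1 cells, as CISH also fell. The list of JAK-STAT feedback genes and STAT3 or STAT5 targets had camera adjusted p = 0.244 with members going both ways, but was lower by fry (adjusted p = 0.0466), so this stays open.

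Macrophage markers were lower and proliferation genes higher with ruxolitinib. Only 2 markers were in the interferon lists or were SIGLEC1, and these do not account for the fall. The other 28 tested markers had a median of -0.54 (camera adjusted p = 4.5e-06), with 19 lower and 3 higher. Any interferon-induced markers outside the fixed lists stay among the 28, so a wider part of interferon in the fall was not excluded. A larger share of undifferentiated THP-1 cells could lower the markers. The summed level of the granule genes MPO, ELANE, PRTN3, AZU1 and CTSG was 1.06 times control (95% interval 0.668 to 1.68). A rise mirroring the median marker fall would be 1.53, which lies inside the interval. That value is only a yardstick, since the rise to look for depends on the share of undifferentiated cells in control, which is not known. Without that share, and with 374 and 340 counts of these genes, a larger share of undifferentiated cells and an effect of the drug on marker transcription cannot be told apart.

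The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05, so the splits give only values. The real split was the 1 of 10 with 4175 genes, against at most 1 gene in the others. For changes of at least 1 on the log2 scale it was the 1 with 571, against at most 1. For the type I interferon, pyroptosis and NF-kB lists it was the 1 with 43, 17 and 28 members past the threshold, against at most 0 in the others. The 3 other splits that also part every batch pair gave at most 1 gene; they differ from the real split in mixing the drug groups. The second principal component (15.2% of the variance) set ruxolitinib replicate 2 apart from control replicate 2 and ruxolitinib replicate 3, and its gene weights had a rank correlation of -0.438 with GC content over 13875 genes.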
